A study of Mus musculus with 3 samples.

How the data were processed

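Single-cell RNA was measured in 3 libraries, 1 per embryonic day (12.5, 14.5 and 16.5), of Oct4-EGFP-positive primordial germ cells from fetal ovaries of C57BL/6 mice. Per the labels' protocols, cells were captured with a 10x Genomics Chromium controller and the version 2 kit for 3' ends, in which UMIs mark single RNA molecules. Per the submitters' processing notes, Cell Ranger 2.0.0, FastQC and the mouse build mm10 (GRCm38) were used. Their settings, and any filter on cells or genes, are not given in the sources used here.

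The authors deposited 1 table of 14133 genes by 19144 cells, whose column names give the stage of each cell. The deposited values are natural log values, ln(1 + UMIs x 10000 / the cell's total). Undoing the natural log gave a total of 10000 in each cell, and 100.0% of the 68606039 non-zero values came within 0.01 of a whole UMI count (largest distance 0.0003). Whole UMIs were recovered in this way. The plan fixed before the data were examined foresaw mean values and differences, with no count model, for a table of log values. Because the counts could be recovered, sums of UMIs were used as the main values instead, and the mean over cells of CPM and the difference of the mean natural log values were kept as alternatives. Cells in the table had between 1998 and 5489 genes and less than 5% mitochondrial UMIs, and each gene was found in at least 87 cells, so the table looks filtered. An upper limit on genes per cell would bear mostly on the E12.5 library, where 21.2% of cells had over 5000 genes, against 0.22% at E14.5 and 1.16% at E16.5.

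Cells needed at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs, which removed 0 cells. Doublets were called per library with Scrublet as built into scanpy, at an expected rate of 6%. The caller marked 38 of 19144 cells (0.20%), far under that rate. Either it did not work or doublets had been removed before, which cannot be told apart here, so doublets may remain. The marked cells were left out. Counts were log-normalised to 10000 per cell, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 0.5 were used over all cells together. The leading genes of a cluster were its 10 genes of largest fold against all other cells. A minimum of 10% of the cluster's cells for a leading gene was set after the clusters were seen, because genes of a few cells led 2 of them (S100a8 and S100a9 in cluster 1, Hbb-bs in cluster 4). Clusters were named from 9 marker lists fixed before the data were examined. A cluster took the type with the largest share of its markers in at least 10% of the cells, unless another type had more markers among the leading genes. The pregranulosa-like cluster had 22 of 24 such markers, 4 of them among its leading genes, beside 31 of 42 germ cell markers. Germ cell markers were among the leading genes of clusters 3 and 7 alone, so the other 8 germ-cell-like clusters rest on the share of markers found. No cluster took a name from the lists for surface epithelium, interstitial, endothelial, blood and immune, erythroid, mesonephric or neural cells.

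For each stage the UMIs of the germ-cell-like cells were summed per gene and given as CPM with exact Poisson 95% intervals. The sums held 125161525, 102506950 and 68980723 UMIs at the 3 stages in time order. For genes of at least 100 CPM the interval's half-width was at most 1.77%, 1.95% and 2.39% of the value. A gene at 0 in 1 stage was set to 3 counts over the group and its ratio given as a bound. With 1 library per stage there was no test, and no p-value was computed. The named genes followed a fixed rule, the 10 with the largest ratio in each direction per comparison among genes of at least 100 CPM in the higher stage. Mitochondrial, ribosomal protein and haemoglobin genes, symbols of the form Gm plus digits (except Gm4969 and Gm960) and symbols ending in Rik were left out. In each list the 4 members of highest CPM and the member with the largest ratio among those of at least 10 CPM were also named, as were Pou5f1, Xist and the genes of the shares. The genes given within the E12.5 library, and the MHC genes named beside H2-D1 and H2-Ab1, were chosen outside this rule after the data were seen. A gene that the rule names for E16.5 over E12.5 is not reported here.

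The 21 lists fixed before the data were examined were pluripotency and early germ cell, meiotic entry, synaptonemal complex and cohesin, meiotic double-strand break and recombination, oocyte differentiation, piRNA pathway and transposon silencing, DNA methylation machinery, S phase, G2 and mitosis, BMP and retinoic acid response, WNT and beta-catenin, apoptosis and DNA damage checkpoint, imprinted genes, oxidative phosphorylation, glycolysis, histone variants and meiotic chromatin, RNA-binding germ cell proteins, X inactivation, Y-linked, male germ line, and immediate-early and heat shock. Some genes stand in more than 1 list. Members needed at least 10 counts over the 3 sums. Each list's median log2 ratio was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these libraries. Numbers of members at least 2-fold higher or lower give size only.

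For shares of cells with a UMI, cells were thinned to 7600 UMIs, the 10th percentile of the shallowest library rounded down, and shallower cells were left out. Exact binomial intervals are given. Gene positions and chromosomes came from GENCODE release M21 (GRCm38), in which 13702 of 14133 symbols (97.0%) were found. X-linked and autosomal genes of at least 10 CPM were compared by their medians. Their ranges, and that of the antigen presentation genes, come from 1000 resamplings of genes and are not counting intervals.

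The steps were tested on simulated data with known answers. Whole counts were recovered for 100.0% of 1087736 simulated values. With 100 genes changed 2-fold and 100 changed 4-fold among 14133 genes, the direction was right for 100.0% in each comparison. The changed genes, equally many raised and lowered, were drawn from those with at least 10 expected counts in each library. Counts carried Poisson error alone, so the errors below cover counting error and not other differences between libraries. At 2-fold, 95% of the absolute log2 errors lay under 0.24 for E14.5 over E12.5, 0.30 for E16.5 over E14.5 and 0.35 for E16.5 over E12.5, and at 4-fold under 0.22, 0.22 and 0.31. The share of 200 unchanged lists of 20 genes outside the central 95% was 5.0% for E14.5 over E12.5, 4.0% for E16.5 over E14.5 and 7.5% for E16.5 over E12.5. These lists were drawn at random from the same ratios as the random lists, so a share near 5% was fixed in advance. It checks the calculation and does not show how lists of genes that vary together would fall.

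Alternatives covered median-of-ratios and TMM scaling, other minimum counts, all cells or all barcodes, a strict cell filter (1500 genes, 3000 UMIs, 5% mitochondrial), doublets kept, equal weight per cell, thinned cells, a CPM total without mitochondrial and ribosomal protein genes, Leiden resolutions of 0.3 and 1.0, and other minimums for shares and X-linked genes. Leaving out the E12.5 cluster with Y-linked UMIs, the difference of natural logs and the shares of pregranulosa-like cells by stage were added after the data were seen. So was the choice of the 5 list medians that stand for the comparisons in the account of the alternatives. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9 were used.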

Results

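Primordial germ cells, the embryonic precursors of the gametes, were profiled by droplet single-cell RNA sequencing at embryonic days 12.5, 14.5 and 16.5 (E12.5, E14.5 and E16.5). Per the labels, the cells were female, came from fetal ovaries of C57BL/6 mice and were sorted for Oct4-EGFP, a reporter of Pou5f1 (Oct4). The series follows the differentiation of these cells, so each stage was compared with the others. Each stage was 1 library with no replicate, and stage and library cannot be told apart. The table held 19144 cells. The E12.5 library had 4706 cells and 125648312 unique molecular identifiers (UMIs), with a median of 26691.5 UMIs per cell. The E14.5 library had 9075 cells and 104214125 UMIs (median 10960), and the E16.5 library had 5363 cells and 69821387 UMIs (median 12659). Cells are not replicates, so no test between stages was made. Intervals of summed UMIs (exact Poisson) and of shares of cells (exact binomial) are 95% intervals that cover counting error only. A count of 0 is given, in place of an interval, the limit that 3 counts set, and a ratio to it the bound at 3 counts.

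After 38 called doublets were left out, the cells formed 11 clusters, of which 10 were germ-cell-like and 1 was pregranulosa-like by markers fixed in advance. The germ-cell-like clusters had 29 to 39 of 42 germ cell markers and 0 to 3 of 24 pregranulosa markers in at least 10% of their cells, and the pregranulosa-like cluster had 31 and 22. Germ-cell-like cells made up 99.5% of E12.5 cells (4678 of 4703), 98.2% of E14.5 cells (8903 of 9069) and 99.6% of E16.5 cells (5312 of 5334). Pregranulosa cells are the somatic supporting cells of the ovary, and Wnt6, Fst, Wt1 and Amhr2 were among the genes that led their cluster, beside the immediate-early gene Cyr61. This cluster held 0.53% of E12.5 cells (0.34 to 0.78%), 1.83% of E14.5 cells (1.56 to 2.13%) and 0.41% of E16.5 cells (0.26 to 0.62%), shares that the reporter sort can set. Most germ-cell-like clusters came from 1 library each. Clusters 0 and 6 held 84.1% and 13.8% of E12.5 cells, clusters 1, 2 and 3 held 32.8%, 31.2% and 31.2% of E14.5 cells, and clusters 4 and 5 held 47.2% and 44.6% of E16.5 cells. A cluster of this kind may be a library and not a cell type, so the stages were compared over all germ-cell-like cells.

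Cluster 6, with 649 cells of the E12.5 library, carried UMIs of Y-linked genes although the library is labelled female. Y-linked UMIs were found in 90.6% of its cells (88.1 to 92.7%; median depth 28436 UMIs) and in 1.94% of the other E12.5 germ-cell-like cells (1.53 to 2.41%). The cluster was singled out for having the largest share of such cells, among clusters formed on the same counts. This contrast is therefore partly built in by the grouping. No such UMI was found at E14.5 (0 of 8903 germ-cell-like cells, which allows a share of up to 0.034%) or at E16.5 (0 of 5312, up to 0.056%). Among the genes that led the cluster were Eif2s3y (chromosome Y, 1010543 to 1028847, GRCm38), at 63.5 counts per 1000000 UMIs (CPM) against 0.52 in the other E12.5 germ-cell-like cells, and Lefty2, a gene of the male fetal germ line, at 199.9 against 5.03. Pou5f1 (655.6 against 685.4 CPM), Dazl (449.6 against 456.2) and Ddx4 (124.1 against 122.7), which are general germ cell genes, stood at similar levels in both.

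**Figure D1:**
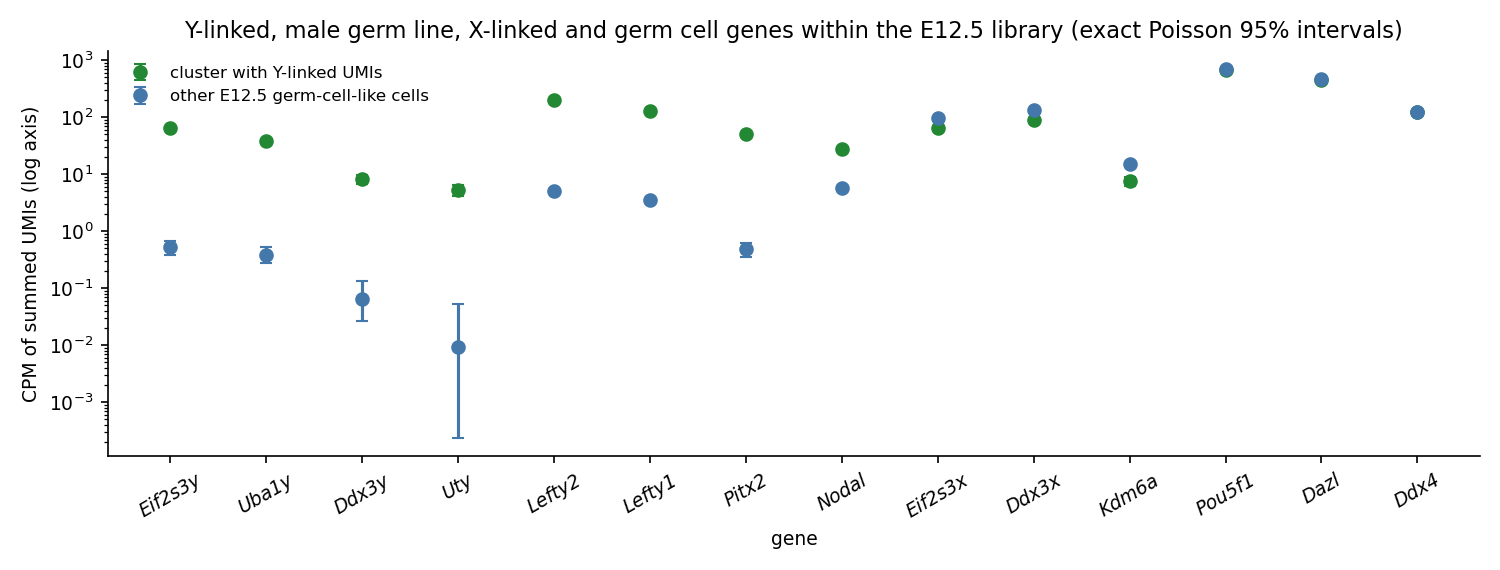
CPM of summed UMIs (log axis) of 14 genes within the E12.5 library, in the cluster with Y-linked UMIs (green) and in the other germ-cell-like cells (blue), with exact Poisson 95% intervals. Eif2s3y stood at 63.5 against 0.52 CPM and Dazl at 449.6 against 456.2 CPM.

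Between E12.5 (mostly clusters 0 and 6) and E14.5 (mostly clusters 1, 2 and 3), meiotic genes were higher and pluripotency genes lower. Stra8, the gatekeeper of meiotic entry (chromosome 6, 34920163 to 34939344), was 444-fold higher at E14.5, at 1457 CPM (1450 to 1465) against 3.28 CPM (2.97 to 3.62). Sycp3, a component of the synaptonemal complex that holds homologous chromosomes together (chromosome 10, 88459569 to 88473236), stood at 689.9 against 39.9 CPM. Pou5f1, the pluripotency factor behind the reporter (chromosome 17, 35506018 to 35510772), was 4.22-fold lower, at 161.4 CPM against 681.0 CPM at E12.5. Nanog, another pluripotency factor, was 19.4-fold lower (3.20 against 62.2 CPM).

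Of the 28 pluripotency and early germ cell genes measured, 25 were at least 2-fold lower at E14.5 and 0 were at least 2-fold higher. Their median log2 ratio was -2.31, at percentile 0 among 10000 random lists matched on expression. Utf1 was 7.04-fold lower (993.2 to 141.0 CPM), Dppa5a 5.55-fold (3705 to 667.7 CPM) and Dppa3 3.21-fold (1386 to 431.4 CPM). The meiotic entry list had 13 of 14 members at least 2-fold higher (median 3.04, percentile 100), among them the meiotic cohesins Smc1b (138.6 to 1630 CPM) and Rec8 (8.64 to 201.6 CPM). In the synaptonemal complex and cohesin list 17 of 18 members were at least 2-fold higher (median 3.75, percentile 100), with Sycp1 25.7-fold and Syce3 18.1-fold higher. In the list of meiotic double-strand break and recombination genes 22 of 28 were (median 3.75, percentile 100). Its members Prdm9, which marks the sites of recombination, Dmc1, the meiotic recombinase, and Rad51ap2 were 165-fold, 14.4-fold and 521-fold higher. The median of all genes was 0.30 under CPM scaling, -0.03 under median-of-ratios scaling and 0.03 under TMM scaling, and the percentiles take each list relative to that shift.

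Genes of the piRNA pathway, which silences transposons, were also higher, 14 of 21 by at least 2-fold, with 1 at least 2-fold lower (median 1.91, percentile 100), with Mael at 369.2 against 50.4 CPM and Gpat2 at 187.7 against 32.9 CPM. The list of RNA-binding germ cell proteins had 12 of 28 members at least 2-fold higher and 5 at least 2-fold lower (median 0.71, percentile 98.8). Dazl, a regulator of translation in germ cells, was 2.52-fold higher and Ybx1 3.77-fold lower. The oocyte differentiation list went both ways, with 7 of 18 members at least 2-fold higher and 7 at least 2-fold lower (median 0.41, percentile 68.4). Only 18 of its 28 genes were measured, and Dppa3 and Kit stand in the pluripotency list too. Figla, a transcription factor of the oocyte programme, was 96.8-fold higher (1.24 to 119.9 CPM) and the tubulin gene Tuba1c 10.4-fold lower.

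Glycolysis genes were lower at E14.5, 13 of 20 by at least 2-fold (median -1.74, percentile 0). Eno1 stood at 30.8 against 328.7 CPM, Pkm at 332.9 against 1111 CPM and Gapdh at 545.6 against 1192 CPM. The oxidative phosphorylation list had a median of 0.23 (percentile 91.4), which was -0.10 under median-of-ratios scaling and -0.04 under TMM scaling, and 26 of its 31 members lay within 2-fold. Ndufa1, of complex I, was 3.63-fold higher and Cox8a, of complex IV, 4.54-fold lower. The S phase list (median -0.60, percentile 0.080) and the G2 and mitosis list (median -0.82, percentile 0) were lower, with the cyclin Ccnb1 at 60.8 against 388.6 CPM. Top2a was at a similar level (322.4 against 319.4 CPM) and Ccne2, a cyclin of S phase entry, was 8.30-fold higher.

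The immediate-early and heat shock list had 12 of 19 members at least 2-fold lower (median -1.24, percentile 0), with the phosphatase gene Dusp1 at 10.0 against 84.2 CPM. In the apoptosis and DNA damage checkpoint list (median -0.40, percentile 1.06) Trp53, which encodes p53, was 9.36-fold lower and the checkpoint kinase gene Atr 5.35-fold higher. Histone variant and meiotic chromatin genes had a median of -0.41 (percentile 0.95), with the nucleosome-binding gene Hmgn5 22.1-fold lower. Lists within the central 95% of random lists were DNA methylation machinery (median 0.49, percentile 76.6), BMP and retinoic acid response (0.48, percentile 79.2), WNT and beta-catenin (0.64, percentile 80.0), imprinted genes (0.62, percentile 85.3) and X inactivation (-0.38, percentile 6.40). Among their members, the methylation cofactor Uhrf1 was 6.69-fold higher, the BMP target Msx1 9.97-fold, and the imprinted gene Dlk1 29.6-fold, and cyclin D1 (Ccnd1) stood at 100.1 against 6.68 CPM.

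The 5 Y-linked genes measured had 0 UMIs at E14.5, so that, at the bound of 3 counts, Eif2s3y was at least 335-fold lower and the list's median was -5.41. The male germ line list had a median of -5.95 (percentile 0), with Lefty2 289-fold lower. Both rested largely on cluster 6, which held 2242 of the 2350 Y-linked UMIs of E12.5 germ-cell-like cells. Without it the male germ line median was -2.60. The Y-linked median was then -3.93, over Eif2s3y and Uba1y alone, with 55 and 41 UMIs at E12.5. Ddx3y, Zfy1 and Uty, with 7, 4 and 1 UMIs, fell below the minimum count of a list member. The Y-linked medians of -5.41 and -3.93 therefore cover different genes.

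Among genes of at least 100 CPM in the higher stage, H2-D1, which encodes an MHC class I heavy chain (chromosome 17, 35262730 to 35267499), had the largest ratio, at 214.6 CPM (211.8 to 217.5) against 0.46 CPM (0.34 to 0.59). Next to Stra8, the other 8 genes with the largest ratios were Taf7l, Spdya, Meioc, Inca1, Tsc22d3, Figla, Dmrtc2 and Tex101, between 69.5-fold and 300.0-fold higher. Taf7l, a germ cell form of a general transcription factor subunit, stood at 345.4 against 1.15 CPM, and Meioc, which sustains the meiotic programme, at 103.6 against 0.48 CPM. The largest ratio in the other direction was that of the metallothionein gene Mt1 (6.35 against 178.0 CPM, 28.0-fold lower), followed by Hmgn5 and Mt2 (15.8-fold lower). Eno1, Tuba1c, Ubald2, Apoe, Trp53, Rrp9 and Tcl1 were between 8.93-fold and 10.7-fold lower. Reads of H2-D1 can be shared with other MHC class I genes, which makes its level uncertain.

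**Figure D2:**
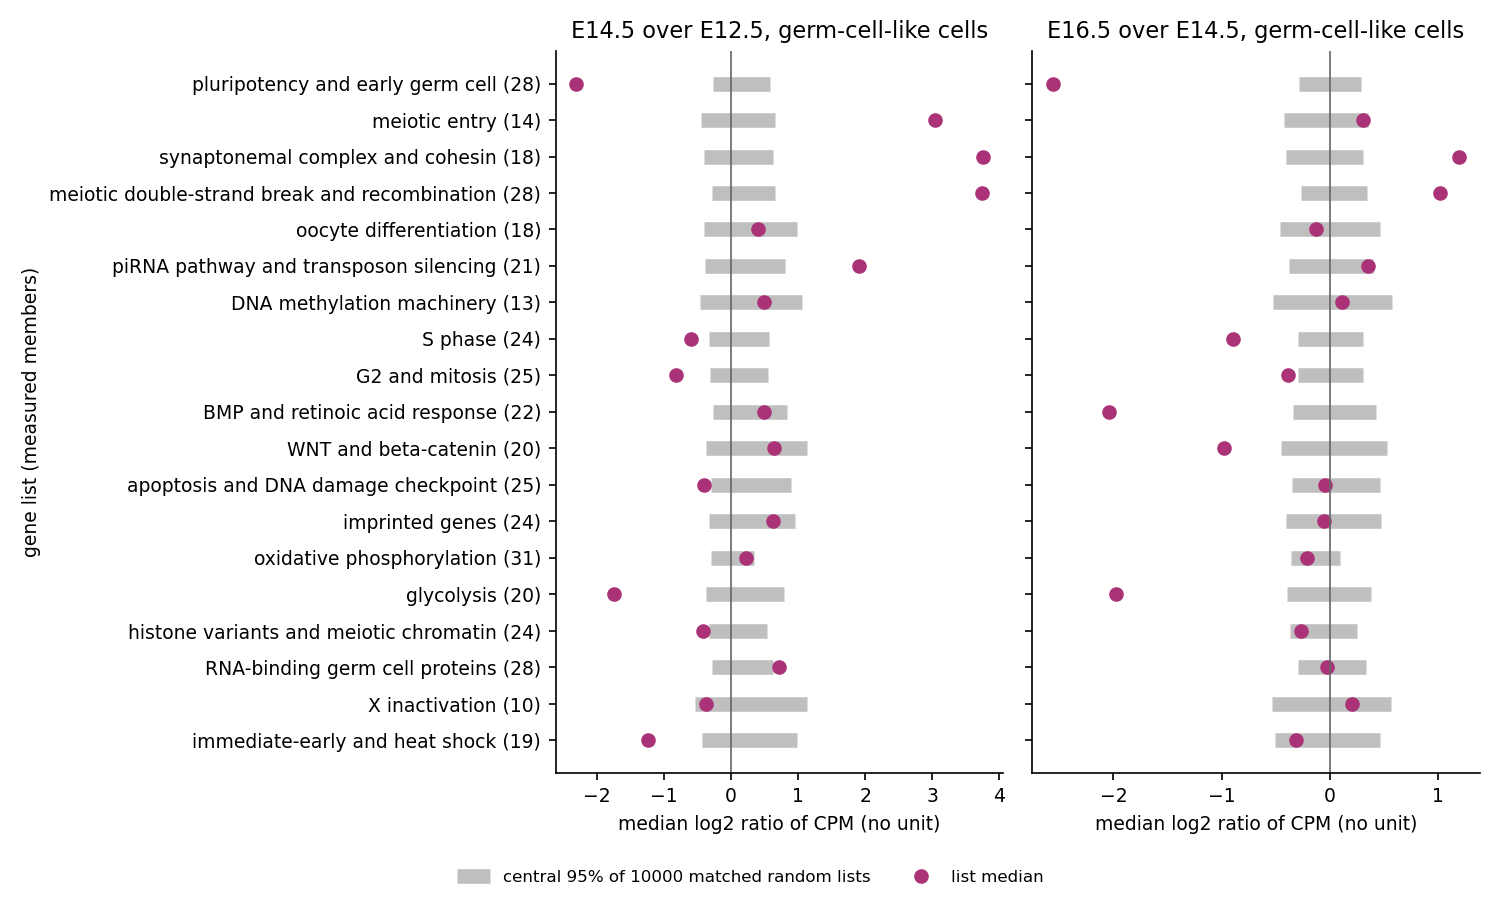
Median log2 ratio of CPM (horizontal axis, no unit) of 19 fixed gene lists (vertical axis, measured members in brackets) for E14.5 over E12.5 and E16.5 over E14.5, with the central 95% of 10000 matched random lists as grey bars. The pluripotency list lay at -2.31 and -2.56, the synaptonemal complex list at 3.75 and 1.19.

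Between E14.5 (mostly clusters 1, 2 and 3) and E16.5 (mostly clusters 4 and 5), the synaptonemal and recombination genes were higher again, while Stra8 and Rec8 were lower. Sycp1, of the transverse filaments of the synaptonemal complex, stood at 1701 CPM against 446.3 CPM (3.81-fold higher). Spo11, which makes the meiotic double-strand breaks, was 5.32-fold higher (33.3 to 177.2 CPM). Stra8 was 5.31-fold lower, at 274.4 CPM (270.5 to 278.3), and Rec8 was 11.1-fold lower (201.6 to 18.1 CPM). Pou5f1 stood at 18.9 CPM, 8.54-fold lower than at E14.5.

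Of the synaptonemal complex and cohesin list 10 of 18 members were at least 2-fold higher at E16.5 and 1 was at least 2-fold lower (median 1.19, percentile 100). Syce3, of the central element, stood at 1150 against 205.5 CPM, and Meikin, a kinetochore regulator of meiosis, at 12.7 against 0.39 CPM. The recombination list had 15 of 28 members at least 2-fold higher and 0 at least 2-fold lower (median 1.01, percentile 100), with Prdm9 2.16-fold and Meiob 3.29-fold higher. Meiotic entry genes went both ways, 2 at least 2-fold higher and 3 at least 2-fold lower (median 0.30, percentile 95.6). The pluripotency list had 25 of 28 members at least 2-fold lower and 1 at least 2-fold higher (median -2.56, percentile 0), with Sox2 at 3.35 against 35.0 CPM and Dppa3 at 43.7 against 431.4 CPM. Phlda2, an imprinted gene in the same list, was 21.8-fold lower.

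Glycolysis genes were lower again, 14 of 20 by at least 2-fold, with 1 at least 2-fold higher (median -1.98, percentile 0), with Aldoa 6.15-fold lower and Ldhb 5.91-fold lower. BMP and retinoic acid response genes, which had gone both ways before, had 15 of 22 members at least 2-fold lower and 0 at least 2-fold higher (median -2.04, percentile 0). Within that list, Rhox5 was 9.96-fold lower, Msx1 7.28-fold lower and Id1, a BMP target, 1.47-fold higher. In the WNT list 10 of 20 members were at least 2-fold lower and 1 at least 2-fold higher (median -0.98, percentile 0.040), with Ccnd1 at 11.6 against 100.1 CPM and Lef1 at 5.68 against 27.1 CPM. The S phase list had 11 of 24 members at least 2-fold lower (median -0.90, percentile 0), with Tyms, of thymidylate synthesis, 4.64-fold lower. The G2 and mitosis list had a median of -0.39 (percentile 0.56), with the centromere gene Cenpa 6.92-fold lower and Cenpf 1.53-fold higher.

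Medians within the central 95% of random lists were found for oocyte differentiation (-0.13, percentile 23.8), piRNA pathway (0.35, percentile 95.8), DNA methylation machinery (0.11, percentile 59.1), apoptosis (-0.04, percentile 29.4), imprinted genes (-0.05, percentile 32.5) and oxidative phosphorylation (-0.22, percentile 30.2). The same held for histone variants (-0.27, percentile 9.72), RNA-binding proteins (-0.03, percentile 32.9), X inactivation (0.21, percentile 74.3), male germ line (-0.57, percentile 10.5) and immediate-early genes (-0.32, percentile 10.9). The DNA methylation median was -0.04 over cells of any cluster, the apoptosis median 0.01 in thinned cells, and the oocyte median 0.01 as a difference of natural logs. Single members still differed, with the demethylation gene Tet1 6.91-fold lower, the cell cycle inhibitor gene Cdkn1a 5.33-fold lower and the oocyte transcription factor gene Lhx8 6.82-fold higher (2.60 to 17.8 CPM). The linker histone gene H1f0 was 8.25-fold higher and the RNA-binding gene Dnd1 10.0-fold lower.

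The genes with the largest ratios of at least 100 CPM at E16.5 were Gc, of the vitamin D binding protein (15.1-fold higher, 11.9 to 180.5 CPM), and Pet2 (9.90-fold). H1f0, Cep290, Syce3, Spo11, Trmt10a, Tktl1, Synj1 and Maoa followed, between 4.35-fold and 8.25-fold higher. Of the genes that were lower, Phlda2 had the largest ratio and Utf1 the next (12.7-fold). Rec8, Rhox5, Dppa3, Sct, Gpx1, Ccnd1, Pou5f1 and Ifitm2 were between 8.24-fold and 11.1-fold lower.

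**Figure D3:**
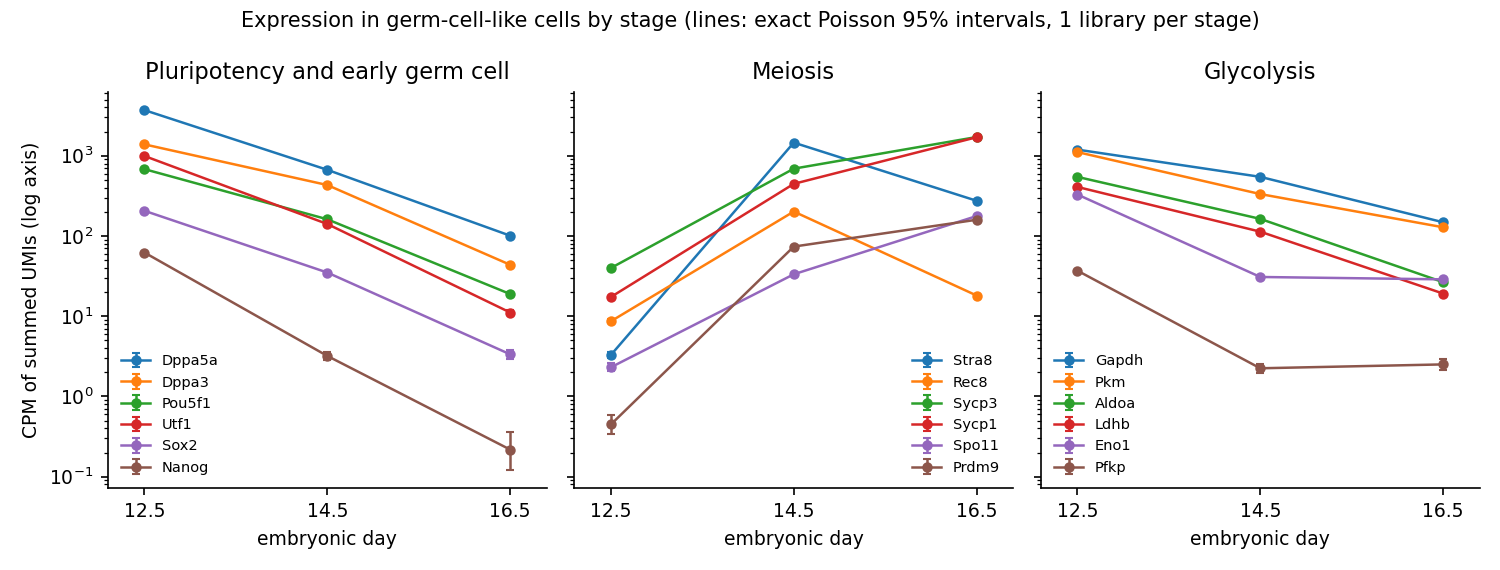
CPM of summed UMIs in germ-cell-like cells (log axis) by embryonic day for 6 pluripotency, 6 meiotic and 6 glycolysis genes, 1 library per stage, with exact Poisson 95% intervals. Stra8 stood at 3.28, 1457 and 274.4 CPM, and Pou5f1 at 681.0, 161.4 and 18.9 CPM.

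Over the whole span from E12.5 (mostly clusters 0 and 6) to E16.5 (mostly clusters 4 and 5), Sycp3 was 42.9-fold higher (39.9 to 1711 CPM) and Sycp1 98.0-fold higher. Prdm9 stood at 159.3 against 0.45 CPM, 356-fold higher. Pou5f1 was 36.0-fold lower, Sox2 61.6-fold lower and Nanog 286-fold lower (0.22 against 62.2 CPM). In the pluripotency list 26 of 28 members were at least 2-fold lower (median -4.98, percentile 0). At least 2-fold higher were 17 of 18 synaptonemal complex genes (median 4.95), 24 of 28 recombination genes (median 4.55), 13 of 14 meiotic entry genes (median 2.95) and 14 of 21 piRNA genes (median 2.53), all at percentile 100. At least 2-fold lower were 1 meiotic entry gene and 3 piRNA genes. Glycolysis genes were lower, 17 of 20 by at least 2-fold (median -3.50, percentile 0), with Hk2, a hexokinase, 39.5-fold lower.

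Medians below the central 95% of random lists were also found for S phase genes (-1.56, percentile 0), G2 and mitosis genes (-1.03, percentile 0.010), BMP and retinoic acid response genes (-1.34, percentile 0.020), immediate-early and heat shock genes (-1.23, percentile 0.22) and histone variants (-0.82, percentile 0.32). The Y-linked and male germ line medians were -4.84 and -5.74. Without cluster 6 they were -3.36 and -3.99, with only Eif2s3y and Uba1y left in the Y-linked list. The Y-linked medians with and without cluster 6 therefore cover different genes. The medians of DNA methylation (0.91, percentile 87.6), RNA-binding (0.59, percentile 89.1), oocyte differentiation (-0.19, percentile 16.1), apoptosis (-0.21, percentile 9.43) and oxidative phosphorylation genes (-0.08, percentile 57.0) lay within the central 95%. Of the last list, Ndufa1 was 11.2-fold higher (217.6 to 2430 CPM) and Atp5b 3.30-fold lower. Also within it, the WNT median of 0.33 (percentile 45.7) was -0.05 under median-of-ratios scaling and -0.03 under TMM scaling. The X inactivation median of 0.07 (percentile 35.0) was -0.31 and -0.30 under these scalings, and the median of imprinted genes of 0.41 (percentile 57.4) was -0.13 over members of at least 100 counts.

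Among genes of at least 100 CPM, the largest ratios were those of H2-Ab1, which encodes an MHC class II chain (chromosome 17, 34257689 to 34269419; 138.4 against 0.072 CPM), and H2-D1 (489.2 against 0.46 CPM). BC051142, Spdya, Taf7l, Ccdc79, Inca1, Prdm9, Meiob and Meioc were between 245-fold and 794-fold higher. Utf1 was 89.3-fold lower. Phlda2, Sox2, Mt1, Ppp1r14b, Ckb, Tcl1, Tst and Hmgn5 were between 43.7-fold and 68.1-fold lower. None of these comparisons has a replicate check.

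Shares of germ-cell-like cells with a UMI were compared after each cell was thinned to 7600 UMIs, which left out 49 cells at E12.5, 843 at E14.5 and 348 at E16.5. Free RNA in the droplets gives UMIs in cells that do not express a gene, so the share in the pregranulosa-like cells (163 after thinning) stands beside each. Doublets with germ cells, where they remained, could add to that share, so it need not measure free RNA alone. Of the pregranulosa-like cells 24 came from E12.5, 118 from E14.5 and 21 from E16.5, so their pooled share reflects mostly the E14.5 library and shares by stage were added after the data were seen. Their median depth before thinning was 8883 UMIs, against 26710.5, 11002 and 12632 in the germ-cell-like cells by stage. Pou5f1 was found in 99.3% of cells at E12.5, 56.0% (54.9 to 57.1%) at E14.5 and 8.30% at E16.5, against 17.2% (11.7 to 23.9%) in pregranulosa-like cells. Of those of E16.5, 2 of 21 held it (1.18 to 30.4%), which leaves open whether the E16.5 share exceeded background. Unthinned, it was found in all 4678 cells at E12.5 and in 61.8% and 12.6% at the later stages. Stra8 was found in 1.86% of cells at E12.5, in 7858 of 8060 at E14.5 (97.1 to 97.8%) and in 45.4% (44.0 to 46.8%) at E16.5. It was found in 0 of 24, 33 of 118 and 10 of 21 pregranulosa-like cells by stage, so that the E16.5 share lay within the interval of the 21 pregranulosa-like cells of its stage (25.7 to 70.2%), which leaves the same open. Sycp3 was found in 24.1%, 88.0% and 99.7% of germ-cell-like cells and in 2 of 24, 39 of 118 and 16 of 21 pregranulosa-like cells. Sycp1 was found in 11.6%, 90.1% and 99.8%, and in 1 of 24, 23 of 118 and 14 of 21 pregranulosa-like cells. Their E12.5 shares lay within the intervals of the 24 pregranulosa-like cells of that stage (1.03 to 27.0% for Sycp3 and 0.11 to 21.1% for Sycp1), which leaves open whether they exceeded background. Rec8 was found in 6.09%, 66.1% and 6.81% of germ-cell-like cells and in 5 of 24, 45 of 118 and 4 of 21 pregranulosa-like cells. At E12.5 its share in pregranulosa-like cells (7.13 to 42.2%) lay above that in germ-cell-like cells (5.42 to 6.82%), so these cells give no background level for this gene.

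Prdm9 was found in 33.7% of cells at E14.5 and 62.3% at E16.5, Dmc1 in 56.2% and 69.4%, Figla in 50.1% and 73.2% and Tex101 in 86.8% and 98.9%. All these shares lay above the intervals of the pregranulosa-like cells of the same stage, of which 15 of 21 at E16.5 held Tex101 (47.8 to 88.7%). Lhx8 was found in 2.10% of E14.5 cells and 10.9% (10.0 to 11.8%) of E16.5 cells, against 0.61% (0.016 to 3.37%) in pregranulosa-like cells. Nobox, another oocyte factor, was found in 2.70% of E16.5 cells and in 0 of 163 pregranulosa-like cells, which allows up to 1.84%. Gm4969 was found in 12.4% of E16.5 cells and in 2.45% of pregranulosa-like cells. Of the pregranulosa-like cells of E16.5, 0 of 21 held Lhx8 or Nobox (up to 14.3%) and 1 held Gm4969 (0.12 to 23.8%), so these cells were too few to set the 3 shares apart from background within the stage. Sohlh1 was found in 0.15%, 2.32% and 5.18% of germ-cell-like cells. At E14.5 it was found in a larger share of the pregranulosa-like cells (14 of 118, 11.9%, with a lower bound of 6.64%), which is therefore no background level for this gene. Dppa5a was found in all 4629 thinned cells at E12.5, in 91.1% at E14.5 and in 38.7% at E16.5. By stage, 14 of 24, 38 of 118 and 4 of 21 pregranulosa-like cells held it (5.45 to 41.9% at E16.5). Utf1 was found in 99.8%, 47.6% and 4.89%, and in 9 of 24, 8 of 118 and 0 of 21 pregranulosa-like cells (up to 14.3% at E16.5). For both genes this leaves open whether the E16.5 share exceeded background. The proliferation genes Mki67 (39.6%, 28.4% and 34.0%; 18 of 163 pregranulosa-like cells) and Top2a (85.6%, 84.2% and 80.1%; 30.1%) differed less between stages. Xist, which silences an X chromosome, was found in 2.53%, 0.22% and 3.06% of germ-cell-like cells and in 98.8% of pregranulosa-like cells. Its CPM in germ-cell-like cells (3.18, 0.41 and 5.20) went the other way between stages over cells of any cluster. Within E12.5, Xist stood at 2.65 CPM (1.96 to 3.50) in cluster 6, which carried Y-linked UMIs. In the other germ-cell-like cells of that stage it stood at 3.27 CPM (2.94 to 3.63). This leaves open whether its E12.5 level exceeded background.

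**Figure D4:**
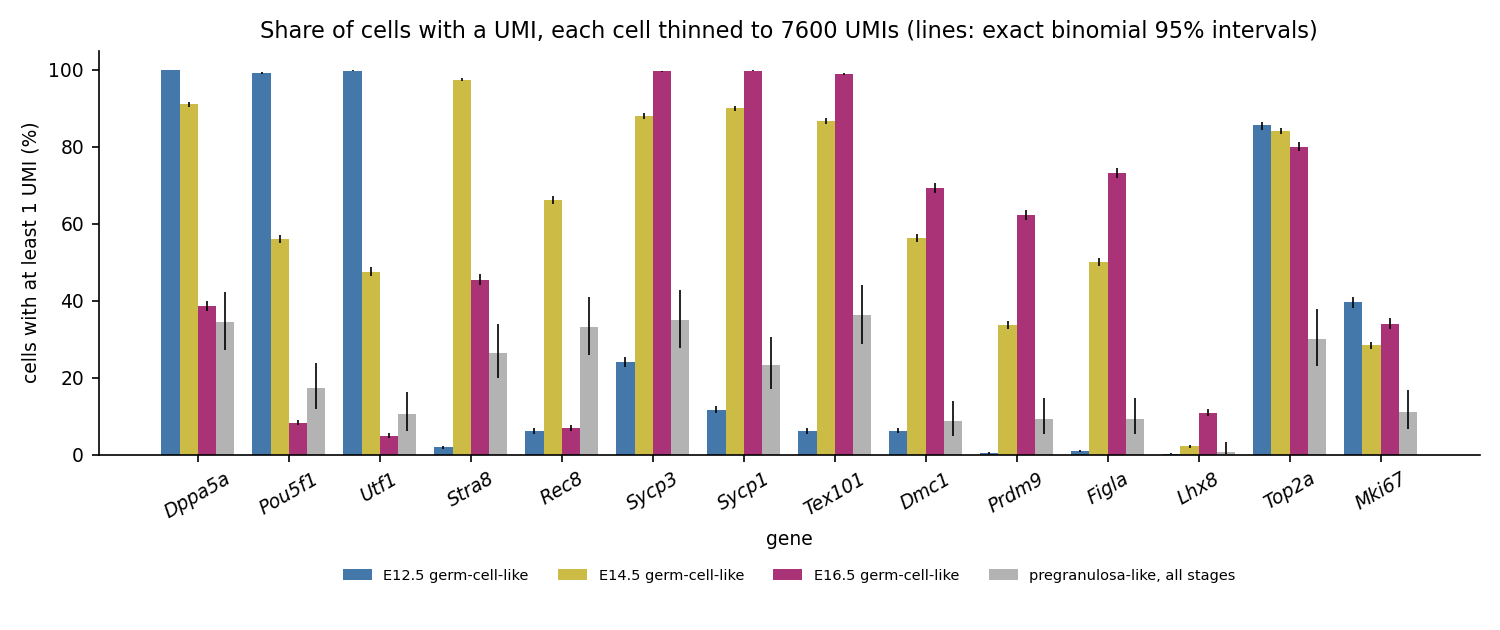
Share of cells with at least 1 UMI (percent, vertical axis from 0) of 14 genes in germ-cell-like cells of each stage and in pregranulosa-like cells, each cell thinned to 7600 UMIs, with exact binomial 95% intervals. Stra8 was found in 1.86% of cells at E12.5, 7858 of 8060 at E14.5 and 45.4% at E16.5, and in 26.4% of pregranulosa-like cells.

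Co-detection of Pou5f1 with the meiotic genes was set against the product of both shares within each stage. At E14.5, 45.7% of cells (44.6 to 46.8%) had UMIs of both Pou5f1 and Sycp3, against a product of 49.2%. Stra8 and Pou5f1 were found together in 54.4% of E14.5 cells (product 54.6%) and in 5.32% of E16.5 cells (4.71 to 5.98%; product 3.77%), where the share of each gene alone lay within the interval of the pregranulosa-like cells of the stage. Sycp3 and Figla were found together in 48.2% of E14.5 cells (47.1 to 49.3%), above the product of 44.1%. At E14.5 the interval of the joint share held the product for Mki67 with Sycp3 (25.1%, product 25.0%). The same held for Stra8 with Sycp3 (86.4%, product 85.8%) and Stra8 with Figla (49.1%, product 48.8%). Stra8 was found in 7858 of 8060 cells of this stage, so a joint share with it can hardly leave the product. For the E14.5 pairs with Stra8, that with Pou5f1 included, a joint share within its interval therefore does not show that the genes are independent. The interval is that of the joint share alone and does not take both single shares as given. Of the 8060 cells, 7858 held Stra8, 7092 held Sycp3 and 6961 held both.

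Female germ cells are known to reactivate their inactive X chromosome, so X-linked genes were compared with autosomal genes. The ratio of the median CPM of 261 X-linked genes to that of 6855 autosomal genes was 0.76 (0.64 to 0.90 over resamplings of genes) at E12.5, 1.05 (0.92 to 1.19) at E14.5 and 1.11 (0.92 to 1.42) at E16.5. From E12.5 to E14.5 the median log2 ratio of X-linked genes exceeded that of autosomal genes by 0.59 (0.37 to 0.81). From E14.5 to E16.5 the difference was -0.10 (-0.18 to 0.03). Without cluster 6 the E12.5 ratio was 0.77.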

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

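In this part, the tests of reads shared with X-linked copies and of free RNA were chosen only after the Y-linked UMIs had been seen. Y-linked UMIs appeared in 14.2% of the E12.5 germ-cell-like cells (13.2 to 15.3%) and stand out because the labels describe the library as female and because the other stages had none. The tables argue against reads of X-linked copies counted on the Y-linked genes, since the E12.5 ratio of Eif2s3y to Eif2s3x would give 305.6 UMIs of Eif2s3y at E14.5, where 0 were found beside 2808 of Eif2s3x. Free Y-linked RNA in the droplets is argued against as well, since at equal depth 34.5% of E12.5 germ-cell-like cells with an Eif2s3y UMI (28.7 to 40.6%) also held another Y-linked gene, 9.97 times the 3.46% (2.94 to 4.04%) of those without. A candidate explanation is that XY germ cells were among the sorted cells, for which X-linked genes lay below autosomal genes in the cluster by a median log2 difference of -0.43 (-0.50 to -0.37 over resamplings of genes; 204 X-linked and 6245 autosomal genes). How such cells might have entered the library, for instance from gonads of male embryos at an age when the sexes are hard to tell apart, was not tested.

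The pregranulosa-like cluster held 0.53% of E12.5 cells, 1.83% of E14.5 cells and 0.41% of E16.5 cells, a signal outside the germ-cell-like cells that were compared.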

How the results depend on the processing

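Leaving out cluster 6, the difference of mean natural logs and the shares of pregranulosa-like cells by stage were alternatives chosen after the data were seen. All 26 list medians of at least 2-fold kept their sign in each of the 13 settings run for lists. Of 806 list medians under an alternative, 559 stayed within the counting interval of the reported value and 247 left it. These totals pool unlike settings. The strict cell filter, a minimum of 1 count and doublets kept left all 62 medians within the interval. The difference of natural logs, on another scale, moved 55 of 62. The sign changed for 13, all of lists within the central 95% of random lists. For the named genes 2986 of 4840 stayed, which includes all 440 under the strict cell filter and all 440 with doublets kept. The sign changed for 24, of which 5 were of genes at least 2-fold apart between the stages. Of the shares of cells 154 of 162 moved with depth or the minimum number of UMIs, and 3 of 18 co-detection ratios moved. Of the 18 pooled shares of pregranulosa-like cells, 15 moved with the cells of E12.5 alone, 0 with those of E14.5 and 15 with those of E16.5. The 18 cell class shares stayed, and the strict cell filter removed no cell and so tests nothing.

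The pluripotency median for E14.5 over E12.5 (-2.31) was -2.64 under median-of-ratios scaling, -2.58 under TMM scaling, -2.48 as a mean over cells of CPM, -2.40 in thinned cells and -2.26 without mitochondrial and ribosomal protein genes. The synaptonemal median (3.75) was 3.43, 3.49 and 4.08 under median-of-ratios scaling, TMM scaling and thinning, and 3.69 without cluster 6. For E16.5 over E14.5 the recombination median (1.01) was 0.96, 0.92, 0.91 and 0.98 under median-of-ratios scaling, TMM scaling, the mean over cells and thinning. For E16.5 over E12.5 the synaptonemal median (4.95) was 4.57 and 4.59 under both scalings. As differences of mean natural logs, which are on another scale, these medians were -0.51, 0.52, 0.18 and 0.84, and the pluripotency median for E16.5 over E14.5 was -0.11.

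The X to autosome ratio was 0.63 at E12.5 with genes of at least 1 CPM and 1.49 at E14.5 with genes of at least 50 CPM, and the cause was not tested. The log2 ratio of Xist reversed with cells of any cluster, to 1.87 for E14.5 over E12.5 (also over all barcodes) and to -1.02 for E16.5 over E14.5 (-1.02 over all barcodes), since these add the pregranulosa-like cells, at 1184 CPM of Xist. Zfy1 reversed to 0.21 for E16.5 over E12.5 without cluster 6, where 4 UMIs at E12.5 are set against the floor of 3 counts at E16.5. Genes of a few CPM are limited by depth most at E16.5, the library with the fewest UMIs.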

Other observations

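In this part, the bound used to read the first 2 tests of X-linked genes, the H2-Ab1 share of pregranulosa-like cells by stage and the removal of H2-Ke6 from the antigen presentation genes were chosen only after the values had been seen. Within the E12.5 library, cells of cluster 6 also differed from the other germ-cell-like cells in early germ cell genes that did not lead the cluster. Dppa5a stood at 5335 against 3423 CPM, Utf1, a chromatin factor of pluripotent cells, at 1270 against 945.2 CPM and L1td1 at 128.8 against 75.4 CPM. Sox2 was lower, at 167.8 against 212.8 CPM, and Nanog close, at 57.9 against 62.9 CPM. X-linked genes with a Y-linked partner were lower, with Eif2s3x at 63.5 against 94.8 CPM and Kdm6a at 7.46 against 14.9 CPM.

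X-linked genes exceeded autosomal genes in their median log2 ratio from E12.5 to E14.5 by 0.59. XY cells in the E12.5 library are argued against as the whole cause. Without cluster 6 the difference was still 0.57 (0.32 to 0.74 over resamplings of genes). In thinned cells it was 0.61 (0.40 to 0.81). Both ranges lie above the 0.2 set for XY cells and for the depth gap, although not wholly above the bound of 0.4 written beforehand. Random thinning leaves the expected CPM of each cell unchanged. The thinned value could therefore hardly fall, and it does not decide on the depth gap. Reactivation of the second X between the stages may contribute and cannot be told apart from a difference between the libraries. The X-linked excess at E12.5 of the cells outside cluster 6 over those in it, 0.43 (0.37 to 0.50), does not decide when it began, since it presupposes that cluster 6 is XY and is the same difference as the one given for that.

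Among genes of at least 100 CPM at E16.5, H2-Ab1 and H2-D1 had the largest ratios over E12.5, and H2-K1, another class I gene, went from 4.16 to 568.0 CPM. Immune cells among the germ-cell-like cells are argued against, since H2-Ab1 was found in 57.9% of thinned E16.5 cells, above the limit of 20% set beforehand, and in 3 of 21 pregranulosa-like cells of that stage (3.05 to 36.3%). A broader gain of antigen presentation genes may be part of it. Of the other 17 such genes measured, 14 were at least 2-fold higher (median log2 ratio 3.39, 1.39 to 5.23 over resamplings of genes). This median was not set against random lists matched on expression. Genes needed at least 10 counts over the 3 sums. H2-DMb1 and H2-Aa, at 0.008 and 0.032 CPM at E12.5, passed only through the later stages, which favours a rise. With H2-Ke6, a dehydrogenase gene of the MHC region, the median was 3.35. Cd74, Tap2 and Psmb8, which the test was also meant to cover, were not among the genes measured. Most of the 17 genes stayed under 10 CPM, with H2-Aa at 1.10 CPM, B2m at 21.8 CPM and Tap1 at 0.54 CPM at E16.5, class I genes can share reads, and stage and library stay confounded here too.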
